A study of Homo sapiens with 6 samples.

How the data were processed

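RNA sequencing measured gene expression in 6 libraries of CAL27, an established oral carcinoma cell line that the labels call adenosquamous. Per the labels, the libraries come from stable lines that expressed GFP-fused proteins and were grown in DMEM with the selection drug G418. The groups are an empty vector, wild-type MB21D2 and MB21D2 with the Q311E substitution, with 2 libraries (A and B) in each. The labels do not say whether A and B are separate cultures, so p-values measure only the spread between these samples, which may be technical.

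The deposited table held FPKM values (reads scaled to gene length and library total) for 30178 human Ensembl gene IDs, as its name says and its values bear out. Per the labels' protocols, total RNA was extracted with QIAGEN material and libraries followed standard Illumina protocols. Per the submitters' processing notes, CASAVA and the mouse builds mm8 and mm9 were involved. The notes give these builds no role, and the IDs are human. The aligner, the counter, the annotation and the use of strand are not given in the sources used here.

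Gene names came from a name table that matched 29993 of the 30178 IDs. Positions, gene types and exon lengths came from GENCODE release 29 on the build GRCh38. Low FPKM values fell on whole multiples of the value of 1 read, so reads could be recovered. Whole reads within a tolerance of 0.001 came out for 30030 genes (99.51%), 22361 of them at exactly the GENCODE 29 length. For the rest, the nearest length that gave whole reads was used, sought from 0.25 to 4 times the GENCODE 29 length, so their length was fitted. Among genes with a mean FPKM of at least 1, 11471 of 11481 (99.91%) gave whole reads. The library total behind the deposited values lay between 20645410 reads (vector B) and 24147306 reads (vector A).

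Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with all 3 groups in 1 fit, a trend in the variance prior and 3 residual degrees of freedom. Genes with a mean FPKM of at least 1 over the 6 libraries entered, 11481 in all. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Every adjusted p for a gene comes from this limma fit. Errors of FPKM values are SDs over 2 libraries and errors of fold changes are SEs. The comparisons, the test, the filter, 38 gene lists, the rule for named genes and 20 alternatives were fixed before the data were examined. Because the values are FPKM, the planned count-based alternative was replaced by limma-voom on recovered reads, which was chosen after seeing the data.

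The 38 lists held 767 symbols, of which 735 matched the table, and 33 lists had at least 5 tested members. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. Member counts are given over all genes tested and also adjusted over the list alone.

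The named genes are MB21D2, then in each comparison the 8 largest rises and 8 largest falls among called genes whose groups did not overlap. They also include up to 4 members of each called list by smallest p, up to 3 passing members of each other list, and 6 genes that moved oppositely in the comparisons with the vector. Genes on the sex chromosomes used to infer sex, unnamed genes and clone, microRNA and small RNA names were left out. The text prints a selection of the 219 genes so named, and says where others were picked later.

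The comparisons with the vector share its 2 libraries. Their overlap was set beside 100 simulated data sets of unchanged groups against shared controls, and beside the overlap of independent lists. The simulation gave each gene the same spread in all 6 libraries. Runs of shifted neighbouring genes were sought with medians over windows of 31 consecutive tested genes, against the 95th percentile of the largest window in 200 permuted gene orders. A list's difference between single libraries was set against 10000 random lists matched on expression.

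The fit was tested on simulated data with 200 changed genes among 11481. For wild type against vector, 92% of genes changed by 1 on the log2 scale and 96% of those changed by 2 were recovered. For Q311E against vector the shares were 83% and 99%, and for Q311E against wild type 89% and 99%. The simulated noise was alike in all libraries, so these shares do not allow for unequal spread. The SD between the 2 libraries was 0.436 for Q311E, against 0.192 for vector and 0.145 for wild type. Calculations outside R used numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.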

Results

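The 6 libraries measured the RNA of CAL27 lines carrying an empty vector, GFP-fused wild-type MB21D2 or GFP-fused MB21D2 Q311E, with 2 libraries each. MB21D2 is a Mab-21 domain protein from the same family as the DNA sensor cGAS, and the Q311E form replaces a glutamine with a glutamate. The series' design text names the comparison of Q311E with the wild-type form, and its title sets it in head and neck squamous carcinoma. The library totals were 24147306 and 20645410 reads for vector A and B, 22805846 and 21325114 for wild type A and B, and 21279535 and 21622498 for Q311E A and B. The SD of the log2 difference between the 2 libraries of a group was 0.192 for the vector, 0.145 for the wild type and 0.436 for Q311E. Values below are mean FPKM ± SD (n = 2), and fold changes are log2 values ± SE with the adjusted p of the limma fit.

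MB21D2 (ENSG00000180611, GRCh38 chromosome 3, 192796815 to 192918161) followed the labels in every library. It stood at 7.73 ± 0.825 FPKM in the vector line, 105 ± 1.0 in the wild-type line and 27.0 ± 8.18 in the Q311E line. The wild-type line was 13.6-fold above the vector (log2 fold change 3.61 ± 0.20, adjusted p = 0.00364), and the Q311E line 3.49-fold (1.65 ± 0.20, adjusted p = 0.00977). The Q311E line thus carried less MB21D2 RNA than the wild-type line (-1.95 ± 0.20, adjusted p = 0.00592), so the form of the protein and its level differ together. FPKM does not tell the Q311E transcript from the wild-type one, nor the introduced gene from the cell's own. Without vector A the adjusted p for wild type against vector was 0.0767, without vector B 0.101, without wild type A 0.088 and without wild type B 0.0812. For Q311E against vector these were 0.0939, 0.0941, 0.0506 and 0.0506, and for Q311E against wild type 0.0779 without wild type A and 0.0765 without wild type B.

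**Figure D1:**
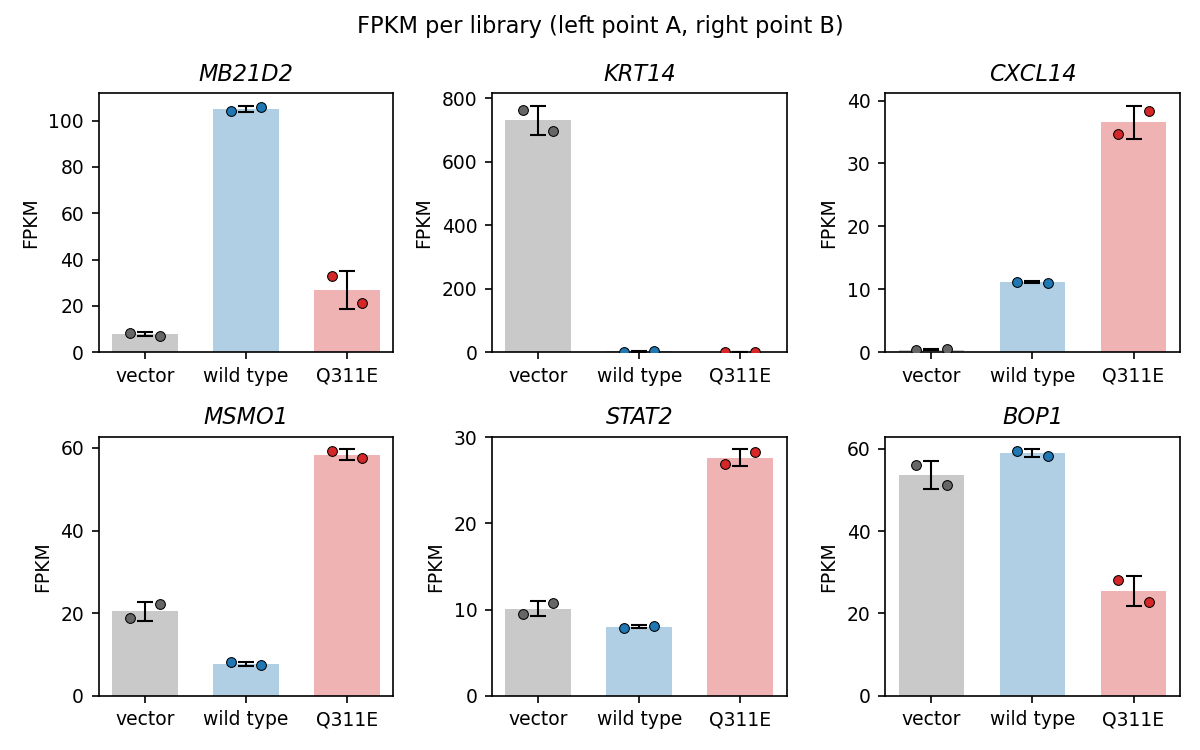
FPKM of MB21D2, KRT14, CXCL14, MSMO1, STAT2 and BOP1 in the vector, wild-type and Q311E lines, with bars for means, error bars for the SD (n = 2) and points for libraries. KRT14 fell from 729 FPKM in the vector line to 2.22 and 0.837 in the other lines, and MSMO1 stood at 20.4, 7.72 and 58.4.

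The comparison of wild type with vector asks which transcripts differ when the wild-type protein is expressed. KRT14, a keratin of basal epithelial cells, fell from 729 ± 46.2 to 2.22 ± 0.19 FPKM (log2 fold change -7.83 ± 0.09, adjusted p = 1e-05), with pseudogene copies that leave its exact level uncertain. IL1A, an inflammatory cytokine, fell from 121 ± 10.5 to 8.92 ± 1.31 FPKM (-3.62 ± 0.37, adjusted p = 0.00965), and the antimicrobial RNASE7 fell by 2.96 ± 0.09 on the log2 scale (adjusted p = 0.0003). CXCL14, a chemokine, rose from 0.409 ± 0.0453 to 11.1 ± 0.106 FPKM (3.10 ± 0.09, adjusted p = 0.0003), and the adhesion molecule L1CAM rose from 0.567 ± 0.0286 to 14.6 ± 0.284 (3.32 ± 0.32, adjusted p = 0.00856). HORMAD2, a meiosis gene, had 12.3 and 12.6 FPKM in the vector libraries and was listed at 0 in both wild-type libraries (adjusted p = 0.0003). In all, 1412 of 11481 genes were called, 406 higher and 1006 lower, and 297 of them changed at least 2-fold.

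Lipid genes were lower in the wild-type line. Of 24 cholesterol synthesis genes 16 fell and 0 rose (23 fell adjusted over the list alone), with a median of -0.81 and a camera adjusted p of 2.62e-11. The sterol enzyme MSMO1 fell by 1.29 ± 0.10 (adjusted p = 0.00659), LSS, which makes lanosterol, by 0.92 ± 0.08 (adjusted p = 0.00744), and INSIG1, a sterol feedback protein, by 2.81 ± 0.24 (adjusted p = 0.00743). Of 14 fatty acid synthesis genes 6 fell and 0 rose (8 fell adjusted over the list alone; median -0.42, camera adjusted p = 0.000266). Among them the desaturase SCD went from 230 ± 34.6 to 29.7 ± 0.599 FPKM. For both lists the adjusted p was 0.479 with an estimated correlation. Of 23 genes of the ATF4 and unfolded protein response, 13 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.51, camera adjusted p = 1.69e-05, and adjusted p = 0.479 with an estimated correlation). XBP1, a transcription factor of that response, fell by 1.17 ± 0.09 and the chaperone-like MANF by 1.09 ± 0.08.

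Immune and epithelial differentiation lists were lower too. Of 15 class I antigen presentation genes 8 fell and 0 rose (8 adjusted over the list alone; median -0.34, camera adjusted p = 5.33e-05, and adjusted p = 0.479 with an estimated correlation). The immunoproteasome subunits PSMB9 (36.5 to 16.1 FPKM) and PSMB8 fell by 1.13 ± 0.08 and 1.00 ± 0.08. Both lie in a stretch of chromosome 6 whose 50 tested genes had a median shift of -0.30. The interferon-stimulated list had a median of -0.45 (camera adjusted p = 0.00979, and adjusted p = 0.701 with an estimated correlation), though only OASL and IFITM1 of its 28 genes fell (2 adjusted over the list alone). Of 11 keratinocyte differentiation genes 6 fell and 1, the protease KLK5, rose (7 and 1 adjusted over the list alone; median -0.95, camera adjusted p = 0.0124, and adjusted p = 0.479 with an estimated correlation). S100A8, a calcium-binding protein of inflamed epithelium, went from 206 ± 78.1 to 1.85 ± 0.0918 FPKM in a stretch of chromosome 1 with a median shift of -0.09 over 47 genes. The list lost its call without genes in shifted chromosomal stretches (adjusted p = 0.127, range over alternatives 0.00121 to 0.127). That removal took out 3 members, among them S100A8, whose own fall helped to set the stretch. The 8 members left had a median of -0.55, with 4 falls and 1 rise, so the lost call does not show that a regional shift lay behind the list. Of 21 p53 targets 6 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.28, camera adjusted p = 0.0358, and adjusted p = 0.479 with an estimated correlation). Their call was lost without vector A and without those stretches (camera adjusted p = 0.072, range over alternatives 0.00596 to 0.072). The p53 median was -0.26 in each case, with 5 falls and 1 rise among the 20 genes left without the stretches. The lost call thus does not show a regional shift or a single library behind the list. Of 28 nuclear oxidative phosphorylation genes 8 fell and 0 rose (11 adjusted over the list alone; median -0.36, camera adjusted p = 5.33e-05, and adjusted p = 0.701 with an estimated correlation). Fold changes in wild type against vector rose with exon length (Spearman 0.226, against 0.092 for Q311E with vector and -0.094 for Q311E with wild type). With each library's trend with exon length removed, an alternative chosen after seeing the data, the oxidative phosphorylation list had 5 falls and a median of -0.23 (camera adjusted p = 0.000749). All 14 lists called in wild type against vector kept their call and direction under it.

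Camera called 6 lists higher in the wild-type line, of which fry called only the immediate early genes (fry adjusted p = 0.037). Fry gave 0.0928 for ERK and EGFR feedback genes and 0.254 for both YAP and TAZ targets and ribosome biogenesis. For G2/M and S phase it gave 0.385 and 0.584. Of 13 immediate early genes 6 rose and 0 fell (7 rose adjusted over the list alone; median 0.97, camera adjusted p = 1.71e-05, and adjusted p = 0.479 with an estimated correlation). The transcription factor EGR1 went from 22.5 ± 9.57 to 160 ± 4.35 FPKM (2.84 ± 0.41, adjusted p = 0.0184), and FOS rose by 2.81 ± 0.52 (adjusted p = 0.0308). Of 19 ERK and EGFR feedback genes 2 rose, the phosphatases DUSP5 (1.11 ± 0.09) and DUSP6 (0.98 ± 0.14), and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.000121, and adjusted p = 0.512 with an estimated correlation). Of 18 YAP and TAZ targets 2 rose, CCN2 (2.04 ± 0.37) and CCN1 (0.76 ± 0.13), and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0022, and adjusted p = 0.701 with an estimated correlation). Medians of 0.26 for 25 G2/M genes, 0.14 for 25 S-phase genes and 0.37 for 23 ribosome biogenesis genes also passed camera (adjusted p = 0.000344, 0.00541 and 6.42e-06, each with adjusted p = 0.701 with an estimated correlation). Of these, limma called the kinase TTK alone as higher (0.75 ± 0.17, adjusted p = 0.0463; in a stretch of chromosome 6 with a median shift of 0.21), and 0 members passed adjusted over the list alone.

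Leaving out 1 library moved the count of 1412 strongly: 11 without vector A, 9 without vector B, 7 without wild type A or wild type B, 5249 without Q311E A and 5262 without Q311E B. Higher calls were 28.8% as deposited, but 504 against 725 (41%) with median scaling and 490 against 626 (43.9%) with quantile normalization. With the length trend removed they were 560 against 710 (44.1%), so the size of the excess of lower calls depended on such choices. It was larger with TPM scaling (270 against 751, 26.4%) and without genes in shifted stretches (196 against 786, 20%). Lower calls stayed the majority in every alternative.

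The comparison of Q311E with vector asks what the substituted form changes. CXCL14 rose to 36.6 ± 2.61 FPKM (log2 fold change 4.73 ± 0.09, adjusted p = 5.7e-05), and LOXL4, a lysyl oxidase of the extracellular matrix, rose from 2.04 to 53.1 ± 20.7 FPKM (4.11 ± 0.29, adjusted p = 0.00349). MUC6, a secreted mucin, rose from 0.0307 to 8.76 FPKM (3.15 ± 0.34, adjusted p = 0.00796). KRT14 fell to 0.837 ± 0.0929 FPKM (-8.63 ± 0.09, adjusted p = 6e-06). FKBP10, a collagen-folding isomerase, fell from 8.03 to 0.524 FPKM (-2.57 ± 0.10, adjusted p = 0.00143), and BASP1, a membrane-bound protein, from 120 to 21.9 FPKM (-2.43 ± 0.18, adjusted p = 0.00429). In all, 2061 genes were called, 995 higher and 1066 lower, and 367 changed at least 2-fold, 238 higher and 129 lower. With TPM scaling 881 calls were higher and 632 lower (58.2% against 48.3% as deposited).

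Interferon and sterol genes were higher in the Q311E line. Of 28 interferon-stimulated genes 10 rose and 0 fell (22 rose adjusted over the list alone), with a median of 1.14 and a camera adjusted p of 5.92e-09 (adjusted p = 0.643 with an estimated correlation). STAT2, which carries interferon signals to the nucleus, went from 10.1 ± 0.795 to 27.6 ± 0.927 FPKM (1.37 ± 0.08, adjusted p = 0.00349), and the regulator IRF7 rose by 1.64 ± 0.27 (adjusted p = 0.0183). The list's median above the vector mean was 1.71 in Q311E A and 0.64 in Q311E B. Of 15 class I antigen presentation genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.55, camera adjusted p = 0.000413, and adjusted p = 0.571 with an estimated correlation). HLA-B went from 136 to 281 FPKM, although reads shared among HLA genes make single members uncertain. Of 24 cholesterol synthesis genes 19 rose and 0 fell (20 adjusted over the list alone; median 0.77, camera adjusted p = 4.45e-11, and adjusted p = 0.571 with an estimated correlation). MSMO1 rose to 58.4 ± 1.21 FPKM (1.48 ± 0.10, adjusted p = 0.00349).

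Immediate early genes rose here too, 6 of 13 with 1 fall (9 and 1 adjusted over the list alone; median 1.25 and 1.89 without Q311E A, camera adjusted p = 0.000366, and adjusted p = 0.643 with an estimated correlation), among them JUN (1.28 ± 0.12, adjusted p = 0.00562). Of 9 replication-dependent histone genes 6 rose and 1 fell, also adjusted over the list alone (median 1.73, camera adjusted p = 0.00516, and adjusted p = 0.571 with an estimated correlation). H2BC12 went from 24.2 to 102 FPKM, in a stretch of chromosome 6 with a median shift of 0.32 over 58 genes, and copies of histone genes leave single members uncertain. Without a filter on low values the histone call was lost (camera adjusted p = 0.0987, range over alternatives 0.000473 to 0.0987). The histone median was then 0.48 over 18 members, of which 3 rose and 0 fell. Of 19 ERK and EGFR feedback genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.00979, and adjusted p = 0.643 with an estimated correlation), with DUSP5 at 1.42 ± 0.09. That call was lost without vector B (0.0528), without Q311E A (0.266, median 0.02 against 0.28) and with a filter of mean FPKM at least 5 (0.0657), in a range of 2.68e-05 to 0.266 over the alternatives. Of 17 PI3K and FOXO genes 1 rose, the insulin receptor substrate IRS2 (0.80 ± 0.14), and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.571 with an estimated correlation). This call was lost without Q311E B, where the median was 0.28 against 0.29. The loss thus does not show that Q311E B carries the list. Of 7 glandular epithelial markers 2 rose, the mucin MUC16 (1.92 ± 0.15) and AGR2 (0.90 ± 0.17), and 0 fell (3 adjusted over the list alone; camera adjusted p = 0.0343, and adjusted p = 0.571 with an estimated correlation; 0.053 without vector A and 0.223 with the stricter filter, range 0.0106 to 0.223).

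Ribosome-making genes were lower, while the cell cycle lists were called with few falling members. Of 23 ribosome biogenesis and MYC target genes 12 fell and 0 rose (17 fell adjusted over the list alone; median -0.64, camera adjusted p = 8.04e-08, and adjusted p = 0.643 with an estimated correlation). BOP1, a ribosome assembly factor, went from 53.6 to 25.5 FPKM (-1.05 ± 0.12, adjusted p = 0.00809), and the nucleolar NOP56 fell by 1.14 ± 0.18 within a stretch of chromosome 20 whose 121 tested genes had a median shift of -0.51. Of 28 nuclear oxidative phosphorylation genes 7 fell and 0 rose (10 adjusted over the list alone; median -0.30, camera adjusted p = 2.59e-06, and adjusted p = 0.667 with an estimated correlation). Of 25 G2/M genes 3 fell and 0 rose (0 adjusted over the list alone; median -0.39, camera adjusted p = 0.000366, and adjusted p = 0.724 with an estimated correlation; 0.054 and a median of -0.10 without Q311E B, range over alternatives 1.01e-08 to 0.054), with the survival protein BIRC5 at -0.62 ± 0.12. Of 25 S-phase genes 4 fell and 0 rose (2 adjusted over the list alone; median -0.29, camera adjusted p = 0.00526, and adjusted p = 0.781 with an estimated correlation; 0.744 and a median of -0.02 without Q311E B, range over alternatives 1.01e-08 to 0.744). Without Q311E A the S-phase median was -0.58. PCNA (-0.64 ± 0.12) and GINS1 (-0.75 ± 0.11), which act at replication forks, both lie in that stretch of chromosome 20.

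The count of 2061 was 3 without vector A or vector B, 269 without wild type A, 270 without wild type B, 5683 without Q311E A and 4417 without Q311E B. The fit shares 1 spread across the groups, and the Q311E pair had the largest SD of the 3 pairs (0.436). SEs may thus be too small in comparisons with Q311E and too large for wild type against vector. Without 1 Q311E library the spread comes from the tighter vector and wild-type pairs, so the larger counts then are no firmer.

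The comparison of Q311E with wild type is the one the design text names, and the vector libraries enter it through the shared spread and the filter on mean FPKM. SCD was at 315 ± 39.5 FPKM in the Q311E line against 29.7 ± 0.599 in the wild-type line (log2 fold change 3.36 ± 0.14, adjusted p = 0.00164), and INSIG1 rose by 3.37 ± 0.24 (adjusted p = 0.0028). The interferon-induced IFI6 stood at 178 ± 127 against 14.0 FPKM (3.37 ± 0.49, adjusted p = 0.0114). PADI2, a protein deiminase, rose by 3.54 ± 0.33 (adjusted p = 0.00483). COL12A1, a fibril-associated collagen, fell from 35.8 to 6.08 FPKM (-2.40 ± 0.20, adjusted p = 0.00397), and ODC1, the first enzyme of polyamine synthesis, from 145 to 44.0 FPKM (-1.74 ± 0.22, adjusted p = 0.00854). In all, 3162 genes were called, 2004 higher in Q311E and 1158 lower, and 617 changed at least 2-fold, 546 of them higher.

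Of 24 cholesterol synthesis genes 23 were higher in Q311E and 0 lower, also adjusted over the list alone (median 1.61, camera adjusted p = 3.91e-15, and adjusted p = 0.388 with an estimated correlation). MSMO1 (2.77 ± 0.10), LSS (1.96 ± 0.08) and DHCR7 (1.64 ± 0.07), which acts at the last step to cholesterol, each had an adjusted p of 0.00164. Of 14 fatty acid synthesis genes 8 rose and 1, FABP5, fell (9 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 0.00204, and adjusted p = 0.425 with an estimated correlation). FASN, the fatty acid synthase, rose by 1.22 ± 0.11, while FABP5, a lipid carrier with many pseudogenes, is uncertain. Of 17 PI3K and FOXO genes 5 rose and 0 fell (10 adjusted over the list alone, median 0.50, camera adjusted p = 0.00399, and adjusted p = 0.388 with an estimated correlation), among them PIK3IP1, an inhibitor of PI3K (1.87 ± 0.42). A filter of mean FPKM at least 5 ended the call (camera adjusted p = 0.107, range over alternatives 0.000924 to 0.107). It left 8 of these genes, with a median of 0.27 and 0 rises. Of 19 hypoxia targets 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.53, camera adjusted p = 0.0155, and adjusted p = 0.79 with an estimated correlation), among them BNIP3L, a mitophagy receptor (1.47 ± 0.31). The hypoxia list stood at -0.02 in Q311E A and 0.68 in Q311E B relative to the vector mean, against -0.46 and -0.40 in the wild-type libraries. Its median was 0.27 without Q311E B.

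**Figure D2:**
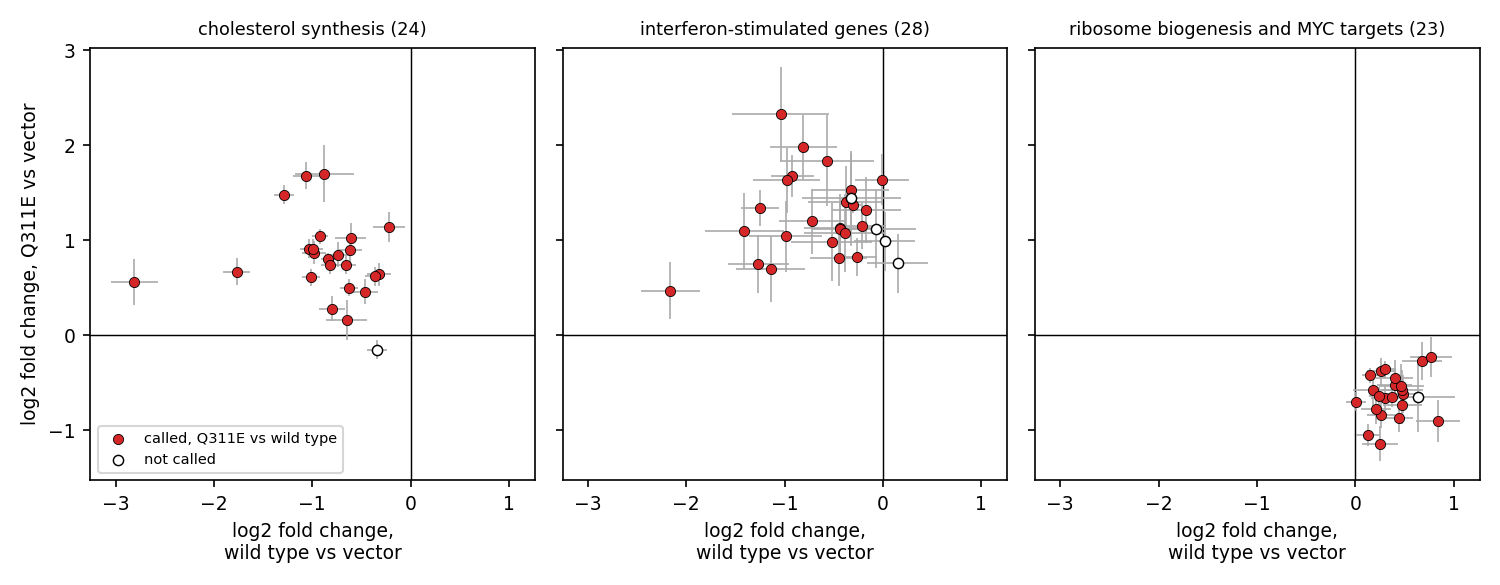
Log2 fold change of each gene of 3 lists in wild type against vector (horizontal) and in Q311E against vector (vertical), with SE bars and genes called between Q311E and wild type in red. Of 24 cholesterol synthesis genes 23 were called higher in Q311E than in wild type, of 28 interferon-stimulated genes 24, and 22 of 23 ribosome biogenesis genes were called lower.

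Of 28 interferon-stimulated genes 24 were higher in Q311E than in wild type and 0 lower (27 adjusted over the list alone; median 1.77, camera adjusted p = 1e-09, and adjusted p = 0.546 with an estimated correlation). STAT2 differed by 1.67 ± 0.08 (adjusted p = 0.00164) and IFITM1, a membrane protein that hinders virus entry, by 2.60 ± 0.19 (adjusted p = 0.00291), in a stretch of chromosome 11 with a median shift of 0.36 over 32 genes. Of 15 class I antigen presentation genes 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.87, camera adjusted p = 2.31e-07, and adjusted p = 0.388 with an estimated correlation). The median shift of this list was 0.89 for its 10 members on chromosome 6 and 0.79 for the 5 elsewhere. Of 12 nucleic acid sensing genes 8 rose and 1 fell, also adjusted over the list alone (median 0.52, camera adjusted p = 0.0112, and adjusted p = 0.388 with an estimated correlation), with the DNA sensor AIM2 at 1.43 ± 0.12 and the RNA sensor family member DHX58 at 2.02 ± 0.19. A filter of mean FPKM at least 5 ended that list's call (0.282, range over alternatives 0.0014 to 0.282). Of 22 NF-kB targets 5 rose and 0 fell (4 adjusted over the list alone; median 0.47, camera adjusted p = 0.00498, and adjusted p = 0.388 with an estimated correlation), among them IL1B (2.38 ± 0.21) and IL1A (2.62 ± 0.37).

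Of 23 ribosome biogenesis and MYC target genes 22 were lower in Q311E and 0 higher (23 lower adjusted over the list alone; median -0.99, camera adjusted p = 1.23e-12, and adjusted p = 0.425 with an estimated correlation), with BOP1 at -1.19 ± 0.12 and the nucleolar chaperone NPM1 at -0.89 ± 0.10. Of 25 G2/M genes 13 fell and 0 rose (22 fell adjusted over the list alone; median -0.57 and -0.35 without Q311E B, camera adjusted p = 1.35e-08, and adjusted p = 0.591 with an estimated correlation), including the mitotic kinase PLK1 (-0.87 ± 0.15). Of 25 S-phase genes 6 fell and 0 rose (11 adjusted over the list alone; median -0.46 and -0.22 without Q311E B, camera adjusted p = 1.59e-06, and adjusted p = 0.721 with an estimated correlation), including the thymidylate synthase TYMS (-0.80 ± 0.20). Of 9 histone genes 6 rose and 0 fell, also adjusted over the list alone (median 1.32, camera adjusted p = 0.00204, and adjusted p = 0.388 with an estimated correlation). Of 21 p53 targets 8 rose and 1 fell, also adjusted over the list alone (median 0.26, camera adjusted p = 0.048, and adjusted p = 0.388 with an estimated correlation), led by CDKN1A, a cell cycle inhibitor (2.05 ± 0.13), and the stress cytokine GDF15 (3.11 ± 0.37). The p53 call was lost in 7 of 21 alternatives, among them without a filter on low values (camera adjusted p = 0.0685, median 0.25) and without wild type A, Q311E A or Q311E B. Leaving out these libraries gave medians of 0.25, 0.33 and 0.38, so those losses do not show that the shift hangs on 1 library.

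The count of 3162 was 969 without vector A, 981 without vector B, 6961 without Q311E A and 4649 without Q311E B. Without wild type A or wild type B the limma calls were lost, in fits that take the lone library to vary like the other pairs. Voom on recovered reads called 3214 genes on all 6 libraries and was not run with a library left out, so it does not bear on that loss. Higher calls were 63.4% as deposited, 1726 against 1595 (52%) with median scaling, and 1331 against 1644 (44.7%) with quantile normalization, which moved the median of all genes from 0.046 to -0.066.

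**Figure D3:**
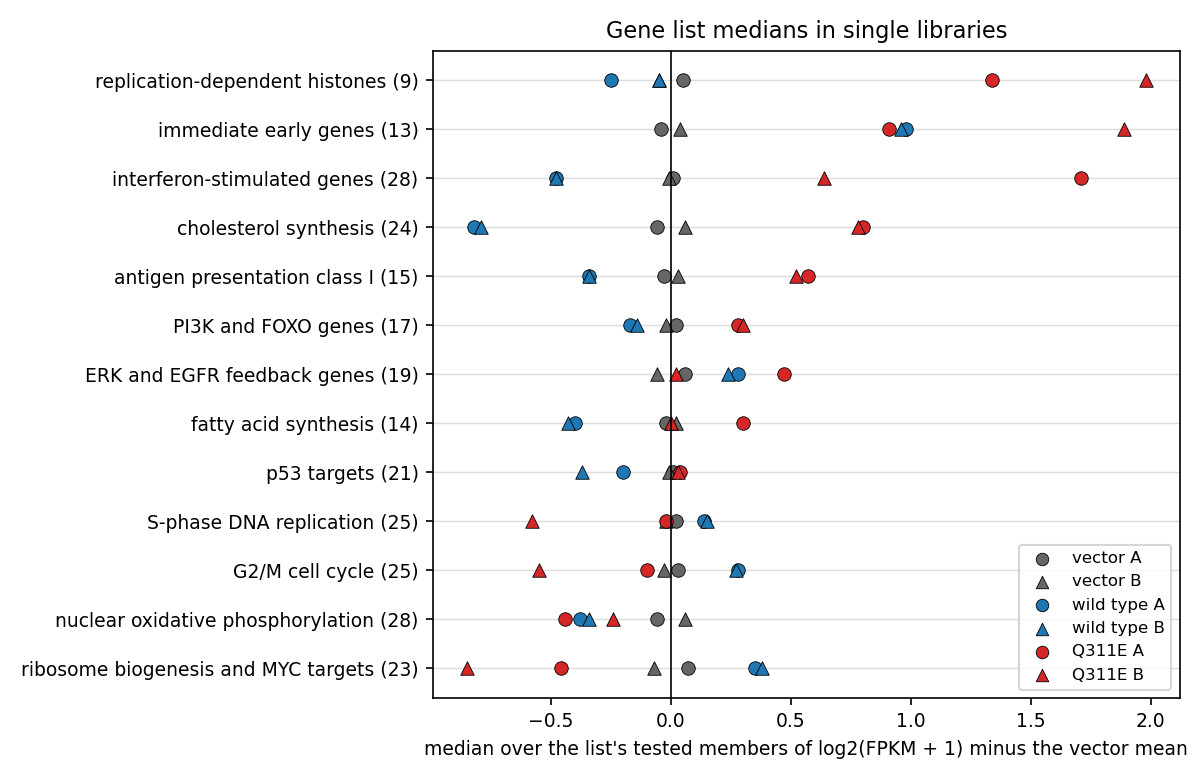
Median log2 difference of each list's genes from the vector mean in each library, for lists called in at least 2 comparisons, with circles for A, triangles for B and member numbers in brackets. The cholesterol list lay at -0.82 and -0.79 in the wild-type libraries and 0.80 and 0.78 in the Q311E libraries, while the interferon list lay at 1.71 in Q311E A and 0.64 in Q311E B.

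Both lines were also set side by side against the vector. In the same direction 520 genes were called in both, 199 higher and 321 lower, where independent lists would share 128.6. That number takes genes to move singly, but 296 genes of chromosome 9 were shifted together in both comparisons (medians 0.52 and 0.47). Without the genes in shifted stretches, a choice made after seeing the data, shared calls were 337 among 10626 tested genes. Part of the overlap may thus come from the vector line and not from MB21D2. Simulated unchanged groups shared 0, which follows from their having almost no calls and gives no measure of the shared controls. Genes that fell in both include KRT14, KRT6A (-3.48 ± 0.11 and -2.68 ± 0.11, uncertain because of near-identical copies) and HORMAD2. Opposite calls numbered 112, below the 124.9 of independent lists, of which 104 were lower in wild type and higher in Q311E, against 87.2 for independent lists, and 8 the reverse, against 37.7. The 112 fell without 1 vector or wild-type library and rose without 1 Q311E library. A lone library is then taken to vary like the other pairs, although the Q311E pair had an SD of 0.436 against 0.192 and 0.145. Counts of calls from such fits thus do not measure what that library carries. On all 6 libraries voom called 120 such genes, and it was not run with a library left out. Library weights gave 155. The number was much smaller without a filter on low values (21), with only the 2 groups compared in the fit (31) and at 2-fold or more (13). KRT17, a stress keratin, fell by 1.19 ± 0.07 in the wild-type line and rose by 0.64 ± 0.07 in the Q311E line, with pseudogene copies that leave it uncertain. Across genes, which are not independent replicates, the fold changes correlated with r = 0.313 and had a covariance of 0.0648. Unchanged groups simulated with shared controls gave 0.501 and 0.0143, a difference of 0.0505 for the covariance. The simulation gave all 6 libraries the same spread, unlike these pairs, so neither simulated value measures the shared controls here. With a separate vector library for each comparison, chosen after seeing the data, r was 0.367 and the covariance 0.0729 with vector A for wild type and B for Q311E, and 0.163 and 0.0381 with these exchanged. Such a split leaves 1 control per comparison, so part of the overlap in shared calls may still come from the shared controls. The 520 shared calls became 3 without vector A or B, 7 without wild type A or B, 1507 without Q311E A and 2106 without Q311E B. The value of r was 0.119 without Q311E A and 0.471 without Q311E B.

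Genes shifted together along parts of several chromosomes, the longest on chromosomes 9 and 20. On GRCh38 chromosome 9, from 94.7 to 138.2 Mb, the 296 tested genes had a median shift of 0.52 in wild type against vector, and 90.2% lay on the higher side. The same genes had a median shift of 0.47 in Q311E against vector and -0.01 in Q311E against wild type. On chromosome 20, from 0.3 to 32.9 Mb, the 121 tested genes had a median shift of -0.51 in Q311E against vector and -0.10 in wild type against vector. Near the start of chromosome 6, overlapping stretches shifted in opposite directions in wild type against vector. The median was -0.61 over 38 tested genes from 0.3 to 10.7 Mb, of which 19 were called lower and 5 higher, and 0.30 over 40 genes from 5.1 to 16.8 Mb. The same stretches had medians of -0.34 and 0.49 in Q311E against vector. The median of the first stretch mixes lower genes toward the chromosome's end with higher genes farther in. The matrix protein TNC (1.59 ± 0.17 and 1.83 ± 0.17) and the transcription factor KLF4 (0.59 ± 0.10 and 1.22 ± 0.10) lie in the stretch of chromosome 9 and rose in both lines.

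**Figure D4:**
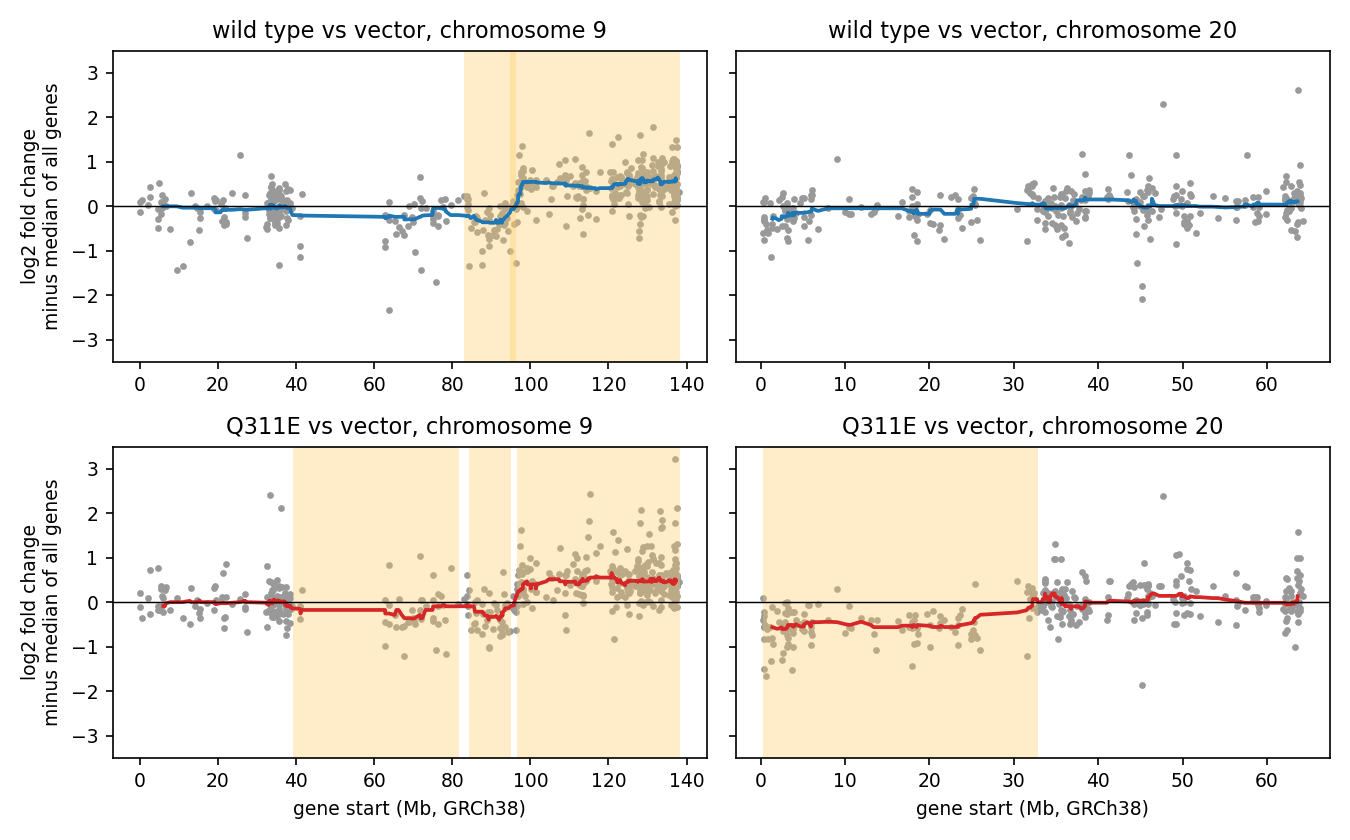
Log2 fold change of tested genes along chromosomes 9 and 20 (position in Mb on GRCh38) for wild type against vector and Q311E against vector, with points for genes, a line for the running median of 31 genes and shading for shifted stretches. The distal part of chromosome 9 lay above 0 in both comparisons (0.52 and 0.47), and the first part of chromosome 20 lay below 0 in Q311E (-0.51).

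Several lists gave no call. Camera called 14, 12 and 13 of 33 lists in wild type against vector, Q311E against vector and Q311E against wild type. Mesenchymal genes had 3 rises and 2 falls among 13 in both comparisons with the vector (camera adjusted p = 0.399 and 0.738), with the matrix protein FN1 at 0.86 ± 0.09 in the wild-type line. Of 19 glycolysis genes 4 rose and 1 fell in Q311E against wild type (camera adjusted p = 0.973). Of 32 cytosolic ribosomal protein genes 0 rose in any comparison, and 1 and 2 fell in the wild-type and Q311E lines (camera adjusted p = 0.79 and 0.106). The ATF4 and unfolded protein response list had 12 falls and 3 rises among 23 in Q311E against vector and no call (adjusted p = 0.0553). Markers of other cell types had too few expressed members to test: 3 of 15 for fibroblasts, 4 of 15 for leukocytes, 1 of 14 for endothelium and 1 of 14 for neural cells and melanocytes. The most abundant of them, picked for their level, were FBLN1 at a mean of 19.9 FPKM, CD74 at 96.7, CDH5 at 21.7 and ENO2 at 1.24.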

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

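The tests of depth, of gene length, of a difference shared by replicate letter and of a steady effect of the MB21D2 level were chosen only after the result was seen. The results here stood out because the wild-type and Q311E lines moved apart from the vector in opposite directions. The direct difference between the lines also passed limma or camera for each, but it follows from the opposite calls by which they were picked and is no separate evidence. Opposite calls covered 112 genes, fewer than the 124.9 of independent lists. On all 6 libraries they numbered 120 with voom and 155 with library weights, but 21 without a filter, 31 with only the 2 groups compared and 13 at 2-fold or more. The count fell without 1 vector or wild-type library and rose without 1 Q311E library, in fits that take a lone library to vary like the other pairs. The 6 of them with the smallest adjusted p differed between Q311E and wild type by 2.77 for MSMO1, 1.96 for LSS, 1.64 for DHCR7, 1.94 for CTSS, 1.93 for KRT86 and 1.82 for KRT17. Reads shared with keratin copies leave KRT86 and KRT17 uncertain. The lists with opposite calls had median differences of 1.61 for cholesterol synthesis, 1.77 for interferon-stimulated genes, 0.87 for class I antigen presentation, -0.57 for G2/M, -0.46 for S phase and -0.99 for ribosome biogenesis. In the libraries taken singly, the cholesterol, interferon, antigen, G2/M, S-phase and ribosome lists kept these opposite signs in both libraries of each line, although the S-phase median was only -0.02 in Q311E A. Without Q311E B the S-phase and G2/M lists were not called against the vector (adjusted p = 0.744 and 0.054, ranges over alternatives 1.01e-08 to 0.744 and 1.01e-08 to 0.054). For 0 of these lists did camera with an estimated correlation give a call (0 of 33 at an unadjusted p under 0.05 in either comparison with the vector). Fry called 13 and 15 lists there, but of these lists only cholesterol synthesis and class I antigen presentation. Its adjusted p for wild type and Q311E against vector was 0.329 and 0.0641 for interferon and 0.385 and 0.221 for G2/M. For S phase it was 0.584 and 0.301, and for ribosome biogenesis 0.254 and 0.0637.

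Cholesterol synthesis genes were lower in the wild-type line and higher in the Q311E line than in the vector line. The list medians lay at -0.06 and 0.06 in the vector libraries, -0.82 and -0.79 in the wild-type libraries and 0.80 and 0.78 in the Q311E libraries. A single Q311E library as the source was argued against by the 22 members above both vector libraries in the Q311E library with fewer, and scaling by list medians that kept at least 0.94 of their size under median scaling. An error common to both vector libraries would move both comparisons alike, so it was not tested apart and may still set where the vector lies between the other lines. A steady effect of the MB21D2 level alone (7.73, 27.0 and 105 FPKM in vector, Q311E and wild type) would place the Q311E line between the others. Only 1 of the 24 members lay there, so the lines as measured were not ordered by level. That count restates the opposite directions by which the list was picked and rests on where the vector lies, so it is no separate test. The form of MB21D2, an effect of level that turns with dose and differences between separately made lines stay open and untested.

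The 2 Q311E libraries differed from each other more than those of the other pairs did, with an SD of 0.436 against 0.192 and 0.145. The ratio of their read totals was 0.984, which argues against depth. The SD stayed at 0.426 after removing the trend with exon length and at 0.393 without the 100 genes with the largest difference, so neither gene length nor a few genes could make up the whole of it. The B minus A differences of the Q311E and vector pairs correlated across genes (r = 0.387), so a factor shared by letter may hold part of the difference and stays open. These differences fell with exon length in the Q311E and vector pairs (Spearman -0.231 and -0.278) and hardly in the wild-type pair (-0.023). How much of the shared part goes with length was not tested. The labels name no batch, and no biological explanation was tested.

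Neighbouring genes shifted together. Windows of 31 genes past the permutation bound numbered 356, 421 and 58 of 10755 in wild type against vector, Q311E against vector and Q311E against wild type, which is what a copy number or clonal difference between the lines would give. The longest stretch, on chromosome 9, was shifted by at least 0.5 in each of the 4 differences between single libraries, so 1 library alone was not its source, and class I antigen genes off chromosome 6 also moved (0.79). Because that stretch was shifted by 0.52 and 0.47 against the vector and by -0.01 between the other lines, it separates the vector line, whereas the stretch on chromosome 20 separates the Q311E line. Copy number may thus differ between the lines, but RNA alone was measured, and a share of the calls may come from the line and not from MB21D2. Short stretches may also be clusters regulated together, class I, class II, S100 and histone genes among them. The class II genes HLA-DRA and HLA-DRB1, picked later, shifted by -1.87 and -1.81 in wild type against vector. In Q311E against wild type they shifted by 1.94 and 2.17, and the other class II genes in that stretch of chromosome 6 moved the same way.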

How the results depend on the processing

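Voom on recovered reads, library weights, separate vector libraries, the removal of 855 genes in shifted stretches and the removal of the trend with exon length were alternatives chosen after seeing the data, while the other alternatives were planned, and the planned count-based quasi-likelihood test was not run because the values are FPKM. No named gene, MB21D2 value or correlation changed sign, but the majority direction of calls turned: in Q311E against wild type from 2004 higher and 1158 lower to 1331 and 1644 with quantile normalization, and in Q311E against vector from 995 and 1066 to 881 and 632 with TPM scaling, 640 and 570 without a filter and 238 and 129 at 2-fold or more, among others. Without a filter the called genes numbered 393, 1210 and 1608 (wild type against vector, Q311E against vector, Q311E against wild type; 30178 genes tested) and shared calls 198. With only the 2 groups compared in the fit they numbered 5273, 262 and 973 with 179 shared, and MB21D2 in Q311E against vector kept a fold change of 1.65 but not its call (adjusted p = 0.0509, range over alternatives 0.00025 to 0.0941). At least 2-fold changes numbered 297, 367 and 617 with 86 shared. Library weights gave 5509, 871 and 2002 calls, and without the shifted stretches shared calls were 337, from fewer genes tested. Camera with an estimated correlation called 0, 0 and 0 lists (0, 0 and 3 unadjusted), where fry called 13, 15 and 16, of which 7, 6 and 10 were camera's. Leaving out each library in turn, with the lone sample assumed to vary like the other groups, gave 7 to 5262, 3 to 5683 and 0 to 6961 called genes (the 0 without either wild-type library, with 2878 and 2794 unadjusted), 3 to 2106 shared calls and r of 0.119 to 0.471. MB21D2 then had fold changes of 3.51 to 3.70, 1.35 to 1.96 and -2.26 to -1.65, with calls lost without a wild-type library in all 3 comparisons and without a vector library in those with the vector. Other values for named genes over all alternatives comprised 5692 with an unchanged call, 1371 with a lost call and 102 with a gained one. Lost calls numbered 236 without each vector library and 273 without each wild-type library. The shared spread bears on these counts, since pair SDs were 0.192 (vector), 0.145 (wild type) and 0.436 (Q311E). Without Q311E in the fit, wild type against vector went from 1412 to 5273 calls. Library weights also raised it and lowered the comparisons with Q311E from 2061 and 3162. SEs may thus be too small with Q311E and too large without it. A lone Q311E library was taken to vary like the tighter pairs, which the SD of 0.436 goes against. Beyond this and the number of genes or samples entering, the cause was not tested. Letters A and B recur in each group without stated meaning: with letter as a replicate block the calls were 1299, 1942 and 3264, and B minus A differences correlated by 0.387 (vector and Q311E), -0.026 (vector and wild type) and -0.006 (wild type and Q311E). Voom called 1491, 2079 and 3214 genes. With the length trend removed the calls were 1270, 2068 and 3487 with 477 shared, and 15, 12 and 15 lists were called. With a separate vector library for each comparison r was 0.367 and 0.163. The scalings turned the direction of no called list. Depth was alike (20645410 to 24147306 reads), and the spread between libraries exceeded counting error, with a chi-square per gene of 13.02, 2.61 and 71.9 for the vector, wild-type and Q311E pairs.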

Other observations

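Single matrix and protease genes were called, although their lists were not in any comparison (camera adjusted p = 0.428, 0.185 and 0.0763 for proteases and 0.0788, 0.661 and 0.598 for collagens and matrix, in the order wild type against vector, Q311E against vector and Q311E against wild type). With the trend with exon length removed, the protease list had an adjusted p of 0.0483 in the last of these. MMP14, a membrane-bound matrix protease, fell by 1.24 ± 0.10 in the wild-type line (limma adjusted p = 0.00715) and was higher in Q311E than in wild type (1.68 ± 0.10, adjusted p = 0.00215). The plasminogen activator PLAU rose by 1.12 ± 0.08 in the Q311E line (adjusted p = 0.00445). FN1, or fibronectin, a member of the mesenchymal list, rose by 0.86 ± 0.09 in the wild-type line (adjusted p = 0.00924) and was lower in Q311E than in wild type (-1.06 ± 0.09). Of 14 matrix proteases and inhibitors 4 rose and 0 fell in Q311E against wild type. STING1, the adaptor downstream of cGAS, fell from 3.95 to 0.541 FPKM in the wild-type line (-1.67 ± 0.26, adjusted p = 0.0211) and stood at 2.78 FPKM in the Q311E line. CGAS itself, picked later, went the other way. Relative to the median of all genes it shifted by 0.82 in wild type against vector and -0.77 in Q311E against wild type. It lies in a stretch of chromosome 6 with a median shift of 0.21 in the former. Of 12 nucleic acid sensing genes 4 fell and 1 rose there (camera adjusted p = 0.0682).

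Keratin 14 was nearly absent from both expressing lines, while its usual partner was not. KRT5, picked after its values were seen, stood at 529 ± 10.5, 411 ± 8.55 and 526 ± 75.5 FPKM in the vector, wild-type and Q311E lines, with limma adjusted p of 0.126 and 0.939 against the vector. FKBP10 (chromosome 17, 41812680 to 41823217) fell with KRT14 (41582279 to 41586921) in both lines, while KRT17 (41619441 to 41624842), which lies between them, stood at 33.4 and 121 FPKM against 77.2 in the vector line. HORMAD2 on chromosome 22 was listed at 0 in both wild-type libraries and in Q311E A, and at 0.018 FPKM in Q311E B.

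The Q311E libraries differed from each other by gene group. The median B minus A difference was -1.10 for interferon-stimulated genes, below all of 10000 random lists, against -0.02 in the vector pair and -0.01 in the wild-type pair. It was 1.03 for immediate early genes, 0.74 for hypoxia targets, -0.56 for S-phase genes and -0.51 for ribosome biogenesis genes in the Q311E pair. For cholesterol synthesis it was -0.12. Mitochondrially encoded genes differed by 0.69 in the Q311E pair and 1.03 in the vector pair. Protein-coding genes above 0 numbered 15044 and 15043 in the Q311E libraries, 14626 and 14633 in the vector libraries and 14393 and 14369 in the wild-type libraries.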
